A study of Mus musculus with 22 samples.

How the data were processed

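Gene expression was measured in the hypothalamus, the brain region that sets body temperature, of male mice labelled IL-6 KO (deficient in the cytokine interleukin-6) and of their wild-type (WT) littermates. The mice, 9 to 12 weeks old, received 1 intraperitoneal injection of lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammation and fever) at 120 µg/kg or of saline, and were killed 3 h later. Per the labels' protocols, the animals were perfused with saline before dissection, RNA was extracted from the hypothalamus, and 200 ng of it was labelled with biotin for an Affymetrix gene array. Arrays were grouped by the treatment and genotype in their labels, which gave 7 WT arrays after LPS, 4 WT arrays after saline, 7 KO arrays after LPS and 4 KO arrays after saline. The labels did not state that each array held the RNA of a separate mouse, so p-values measure the spread between arrays. Replicates were numbered in deposition order and no array was paired with another.

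The authors deposited 1 table of log2 values for 28815 probe sets on 22 arrays. RMA, a method that corrects the background, quantile-normalizes the arrays and summarises probes, was named without a version, per the submitters' processing notes, and the genome build and annotation release were not given in the sources used here. The values themselves showed a further step by the authors: every probe set's median over the 22 arrays was 0 to within 7.02e-07, so each value states how far an array lay above or below the median array. The table therefore held differences between arrays and no level of a gene, and no gene's level was set against another's. The base of the logarithm was not stated. It was taken as 2 because 99.9% of 619801 values between 0.001 and 0.5 in size were whole multiples, within a tolerance of 0.03, of the step that a single-precision number between 4 and 8 has, and such levels are those of log2 RMA values. Column medians lay between -0.01 and 0.03, no pair of arrays held identical values, and the highest correlation between 2 arrays over genes was 0.601. Arrays have no read depth, so their number limits the precision.

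Probe sets were named through the platform annotation given with the data, with symbols updated by gene ID through a RefSeq table of assembly GRCm38.p6, in which 21689 of 21780 probe sets with 1 symbol matched. A further 1605 probe sets listed several symbols and 5430 listed none; these 7035 were left out of the gene-level tests. Probe sets of one gene were averaged, which affected 998 genes, and 19935 genes were tested. The plan made before the data were examined had chosen the brightest probe set per gene, a filter on dim genes and a variance trend with intensity; centring removed the levels that all 3 need, so the average was used in their place and the filter and trend were not run. The authors' build was not named, so no coordinates are printed and the reference served for names and for which genes lie near Il6.

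The tests used limma 3.58.1 in R 4.3.3: 1 mean per group over all 22 arrays, empirical Bayes moderation with default settings, two-sided tests of 5 contrasts, and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. The contrasts were KO against WT under LPS, LPS against saline in each genotype, KO against WT under saline, and the interaction, which tests whether the LPS effect differs between genotypes. Errors given with log2 differences are standard errors (SE) of the fit, and those given with group means are SDs. A response score per array was the mean over genes called in the LPS effect averaged over both genotypes, and its genotype difference was tested by exact permutation within treatments. Gene lists, 27 in number and fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes, with an estimated correlation and limma's fry as alternatives, and by exact permutation of each array's mean over a list. Genes called in the genotype effect averaged over treatments were tested for location within 20 Mb of Il6 with Fisher's exact test, two-sided.

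The text names, by a rule written before the data were examined, the 15 largest increases and 10 largest decreases called in a contrast, up to 4 called members of each list or, where none was called, 1 or 2 with the smallest p, the 3 smallest p per direction where none was called, called genes near Il6, and always Il6, Lcn2, Ptgs2, Ptges, Socs3, Il1b, Tnf, Il6ra and Il6st. Most uncalled list members that the rule selects were left out for length, which departs from it; other exceptions are marked where they occur.

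The tests were tried on simulated data with 19935 genes in the same groups, of which 200 had planted changes. The noise was drawn independently for each gene and array. It lacked correlation between genes and the differences by array number found in the real arrays, so the rates below may not hold for them. For KO against WT under LPS, 64.2% of genes planted at 0.25 log2 units and 100% of those at 0.5 were recovered, with 12 false calls. For LPS in WT the shares were 53.7% and 97.0% with 9 false calls, for LPS in KO 43.3% and 97.0% with 10, and for KO against WT under saline 38.8% and 91.0% with 11. For the interaction, 16.4% at 0.25, 76.1% at 0.5 and 98.5% at 1 were recovered, with 7 false calls.

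The sample titles carry array numbers 1 to 22, of unstated meaning. Of arrays 1 to 11, 8 were WT, and of arrays 12 to 22, 8 were KO, so the genotypes are partly confounded with this number. After this was seen, fits with the array number as a covariate, with array block (1 to 11 or 12 to 22) as a term, and within each block were added, as were fits without arrays high in choroid plexus or pituitary genes. Alternatives fixed beforehand were another quantile normalization, centring each array on its median, array weights, all probe sets in place of genes, a fold threshold, fits of the compared groups alone, an unmoderated test with unequal variances, and leaving out each array in turn.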

Results

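Expression in the hypothalamus was compared between 22 arrays, of which 7 came from WT mice after LPS, 4 from WT mice after saline, 7 from IL-6 KO mice after LPS and 4 from IL-6 KO mice after saline. The design text names the question: whether genes that differ between the genotypes after LPS could account for the missing fever response of mice without IL-6. Values are log2 differences from each probe set's median over all arrays. Genes of neighbouring tissues marked a few arrays. Ttr, a product of the choroid plexus, lay at 4.62 in WT saline replicate 1 and at 2.80 in WT LPS replicate 5. The pituitary hormone genes Gh and Prl lay at 3.96 and 2.90 in KO saline replicate 2, and at 3.76 and 2.74 in KO LPS replicate 3. These 3 genes were chosen after their values were seen. Array number was related to many genes. In a fit with the 4 groups, 4286 of 19935 genes differed between arrays 1 to 11 and arrays 12 to 22 at an adjusted p under 0.05, so genotype results are given with and without these array blocks as a term in the fit.

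The targeted gene was examined first. The Il6 value did not separate the genotypes. After LPS it was 0.07 ± 0.14 (SD, n = 7) in WT and 0.24 ± 0.20 (SD, n = 7) in arrays labelled KO, a difference of 0.17 (SE 0.07, adjusted p = 0.397, limma). After saline it was -0.14 ± 0.04 (SD, n = 4) in WT and -0.12 ± 0.04 (SD, n = 4) in KO. Il6 rose with LPS in KO by 0.36 (SE 0.08, adjusted p = 0.0193, limma), while in WT the difference was 0.21 (SE 0.08, adjusted p = 0.457). Of 31 alternative fits, the KO call was lost in 6. The LPS effects of the genotypes did not differ by the interaction test (0.15, SE 0.12, adjusted p = 0.999994, limma). The labels did not say which part of the gene was altered, so a probe set that may lie outside that part checks nothing. Genes near Il6 did differ between the labelled genotypes, as the last paragraph gives.

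LPS changed 359 genes in the WT hypothalamus, 284 higher and 75 lower. Interferon-stimulated genes made up many of the largest increases, and genes of brain endothelial cells many of the largest decreases. The largest increase was in Cxcl10, a chemokine that attracts T cells, which was 29.5-fold higher (log2 4.88, SE 0.19, adjusted p = 1.89e-14, limma). Rsad2, an antiviral interferon-induced enzyme, was 10.6-fold higher, and Lcn2, an acute-phase protein that binds bacterial iron carriers, was 10.5-fold higher (log2 3.39, SE 0.20). The interferon-induced GTPases Gbp5 and Gbp4 were 8.77-fold and 7.46-fold higher, Ifit1 6.49-fold and Iigp1 6.12-fold. The other large increases were in Slfn5, Ifit3, AW112010, Parp14, Ifit2, Trim30a, Gbp3 and Gbp9, with log2 differences from 2.29 for Slfn5 down to 1.80 for Gbp9.

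Among lists fixed beforehand, 26 of 28 measured interferon-stimulated genes rose in WT, both over all genes and adjusted over the list alone (median log2 1.21, camera adjusted p = 6.92e-132, and adjusted p = 4.06e-06 with an estimated correlation). Of 17 glucocorticoid-responsive genes, 14 rose (15 higher and 1 lower adjusted over the list alone; adjusted p = 2.67e-06 with an estimated correlation). They included the kinase gene Sgk1 (log2 1.68, SE 0.08), Zbtb16 (1.43, SE 0.14), the metallothionein Mt2 (1.16, SE 0.15) and Errfi1 (1.09, SE 0.14). The STAT3-linked and acute-phase list, genes known to respond to IL-6 family cytokines or to be part of the acute-phase response, had 12 of 28 members called higher (15 adjusted over the list alone; adjusted p = 0.00224 with an estimated correlation). Besides Lcn2 these included the copper carrier ceruloplasmin, Cp (log2 1.08, SE 0.22), Steap4 (0.80, SE 0.10) and the transcription factor Cebpd (0.41, SE 0.07). Of 28 genes of TLR4 and NF-kB signalling, 9 rose (15 adjusted over the list alone; adjusted p = 0.00194 with an estimated correlation), among them the NF-kB inhibitor Nfkbia (log2 1.36, SE 0.13), Birc3 (1.03, SE 0.13), Map3k8 (0.73, SE 0.09) and Tnfaip3 (0.72, SE 0.14).

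Of 24 chemokines, 8 rose and 1 fell in WT (12 and 1 adjusted over the list alone; adjusted p = 0.00224 with an estimated correlation). Ccl2 rose by 1.30 (SE 0.33), Ccl12 by 1.17 (SE 0.12) and Cxcl11 by 1.16 (SE 0.13). Of 24 other cytokines and receptors, 5 rose (9 adjusted over the list alone; adjusted p = 0.00198 with an estimated correlation), including Il17ra (0.39, SE 0.06), Csf1 (0.37, SE 0.08), Il15 (0.37, SE 0.09) and Tnfrsf1b (0.30, SE 0.07). Il1b did not pass the test in WT (0.39, SE 0.13, adjusted p = 0.189), nor did Tnf (0.09, SE 0.05, adjusted p = 0.9997). Of 13 genes of the IL-6 cytokine family and its receptors, 3 rose, over all genes and adjusted over the list alone (adjusted p = 0.0236 with an estimated correlation). They were the receptor genes Osmr (1.23, SE 0.15), Lifr (0.39, SE 0.07) and Il6ra (0.30, SE 0.06). Il6st, which encodes the shared receptor chain gp130, had a difference of 0.06 (SE 0.06, adjusted p = 0.9997). Socs3, the feedback inhibitor of IL-6 signalling, had 0.26 (SE 0.08, adjusted p = 0.135).

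The prostaglandin E2 genes moved in both directions. Ptgs2, which encodes the inducible cyclooxygenase, rose 2.93-fold in WT (log2 1.55, SE 0.22, adjusted p = 8.15e-05, limma) and Ptges, the terminal synthase, 1.28-fold (log2 0.36, SE 0.09, adjusted p = 0.0467). Of 31 alternative fits, the Ptges call was lost in 20, and that of Ccl2 in 19. Hpgd, which degrades prostaglandins, fell by 0.33 (SE 0.07, adjusted p = 0.00601). The list of 18 measured genes had 2 called higher and 1 lower, with the same counts adjusted over the list alone, and as a set it did not pass the test (camera adjusted p = 0.857), with a median of -0.01 and a mean of 0.07.

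Endothelial genes split into rising activation genes and falling cell markers. Of 15 endothelial activation genes, 6 rose in WT (8 adjusted over the list alone; adjusted p = 0.00162 with an estimated correlation), including the cholesterol hydroxylase Ch25h (1.34, SE 0.16) and the adhesion molecules Icam1 (1.20, SE 0.13), Vcam1 (1.11, SE 0.12) and Sele (0.50, SE 0.09). Of 16 endothelial cell markers, 9 fell (adjusted over the list alone, 11 fell and 2 rose; adjusted p = 0.000181 with an estimated correlation). The organic anion transporter Slco1a4 fell by 1.43 (SE 0.15), the tight-junction protein gene Cldn5 by 1.14 (SE 0.11), the angiopoietin receptor Tek by 0.74 (SE 0.08) and the drug exporter Abcb1a by 0.57 (SE 0.07). The other large decreases were in the iron exporter Slc40a1 (-0.93, SE 0.12), Ranbp3l (-0.89, SE 0.21), the thyroid hormone transporter Slco1c1 (-0.74, SE 0.10), Trim59 (-0.66, SE 0.13), Rasgrp3 (-0.60, SE 0.09) and Kdr (-0.56, SE 0.07).

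The microglia and macrophage markers were lower as a set (adjusted p = 0.0236 with an estimated correlation), with 1 of 16 members called, the fractalkine receptor Cx3cr1 (-0.46, SE 0.08; 3 lower adjusted over the list alone). Immediate early genes were higher as a set (adjusted p = 0.0445 with an estimated correlation), with Atf3 alone called of 21 (0.54, SE 0.07; 5 adjusted over the list alone). Called single genes of other lists were the complement receptor C5ar1 (0.40, SE 0.06; 2 of 13 complement genes adjusted over the list alone), the thyroid hormone activating enzyme Dio2 (0.53, SE 0.08; 1 of 24), and the clock genes Ciart (0.30, SE 0.07) and Dbp (-0.22, SE 0.06; 2 higher and 1 lower of 17). The camera calls for complement, for energy-balance receptors and for choroid plexus markers were lost with an estimated correlation (adjusted p = 0.137, 0.192 and 0.445). Heat-shock genes, cold-inducible genes, neuropeptides, blood cell markers, and markers of neurons, astrocytes, oligodendrocytes, pericytes, pituitary, thalamus or hypothalamic regions had no called member in WT.

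Fitted with array block as a term, 432 genes were called, including all 359. Within arrays 1 to 11 (5 LPS and 3 saline) 350 were called, and within arrays 12 to 22 (2 LPS and 1 saline) 45, where the spread came from the other groups for want of a further WT saline array.

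In KO mice LPS changed 267 genes, 216 higher and 51 lower. Cxcl10 was 21.3-fold higher (log2 4.41, SE 0.19), Rsad2 11.1-fold (3.47, SE 0.15), Gbp5 8.75-fold (3.13, SE 0.13) and Gbp4 8.39-fold (3.07, SE 0.09; adjusted p = 2.38e-17, limma). Iigp1 rose by 2.59, AW112010 by 2.51, Ifit1 by 2.44, Lcn2 by 2.31 (SE 0.20), Slfn5 by 2.27, the death ligand gene Tnfsf10 by 2.10, Ifit3 by 1.99, Parp14 by 1.90, Gbp3 by 1.83, Sgk1 by 1.80 and Ifit2 by 1.62. Of 28 interferon-stimulated genes, 25 rose (26 adjusted over the list alone; adjusted p = 3.47e-06 with an estimated correlation). Of 17 glucocorticoid-responsive genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 3.47e-06 with an estimated correlation), including Sgk1 (1.80, SE 0.08), Zbtb16 (1.46, SE 0.14), Errfi1 (0.91, SE 0.14) and Fkbp5 (0.87, SE 0.11).

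The STAT3-linked and acute-phase list had 3 of 28 members called in KO (10 adjusted over the list alone; adjusted p = 0.0137 with an estimated correlation): Lcn2, Steap4 (0.60, SE 0.10) and Il4ra (0.30, SE 0.06). Of TLR4 and NF-kB genes, 9 of 28 rose (15 adjusted over the list alone; adjusted p = 0.00594 with an estimated correlation), with Nfkbia at 1.35 (SE 0.13), Birc3 at 0.68 (SE 0.13), Tlr2 at 0.58 (SE 0.12) and Tnfaip3 at 0.56 (SE 0.14, adjusted p = 0.0375). Chemokines had 4 called higher and 1 lower of 24 (12 and 1 adjusted over the list alone; adjusted p = 0.00594 with an estimated correlation), including Ccl12 (0.86, SE 0.12), Cxcl11 (0.81, SE 0.13) and Ccl9 (0.45, SE 0.09). Osmr (0.96, SE 0.15), Lifr (0.27, SE 0.07) and Il6 itself were called of the 13 IL-6 family genes (4 adjusted over the list alone, and adjusted p = 0.0108 with an estimated correlation). The Lifr call was lost in 11 of 31 alternative fits and the Il6 call in 6. Csf1 (0.48, SE 0.08) and Il15 (0.40, SE 0.09) were called of 24 cytokines and receptors, as they were adjusted over the list alone (adjusted p = 0.069 with an estimated correlation). Il1b (0.31, SE 0.13, adjusted p = 0.600), Tnf (0.04, SE 0.05), Socs3 (0.15, SE 0.08, adjusted p = 0.950), Il6ra (0.24, SE 0.06, adjusted p = 0.0693) and Il6st (-0.02, SE 0.06) did not pass.

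Ptgs2 rose 2.55-fold in KO (log2 1.35, SE 0.22, adjusted p = 0.000617) and Hpgd fell by 0.42 (SE 0.07), whereas Ptges had a difference of 0.20 (SE 0.09, adjusted p = 0.831). The difference between genotypes in the Ptges effect was -0.16 (SE 0.13, adjusted p = 0.999994), and in the Ptgs2 effect -0.20 (SE 0.32, adjusted p = 0.999994). Of endothelial activation genes, 3 of 15 rose (7 higher and 2 lower adjusted over the list alone; adjusted p = 0.0137 with an estimated correlation): Vcam1 (1.31, SE 0.12), Icam1 (1.25, SE 0.13) and Ch25h (1.005, SE 0.16). Of endothelial cell markers, 7 of 16 fell (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.000417 with an estimated correlation), with Slco1a4 and Cldn5 both falling by 1.08 (SE 0.15 and 0.11) and Tek by 0.65 (SE 0.08). Trim59, Slc40a1, Sox2, Ptprb, Kdr, Egfl7 and Slco1c1 were the other large decreases, between -0.78 and -0.48. Atf3 (0.45, SE 0.07), Dio2 (0.46, SE 0.08) and C5ar1 (0.40, SE 0.06) also rose in KO. Immediate early genes were higher as a set (adjusted p = 0.0471 with an estimated correlation), while the camera calls for complement and for clock genes were lost (adjusted p = 0.0925 and 0.397 with an estimated correlation). Microglia markers did not pass as a set (camera adjusted p = 0.400), and Cx3cr1 had -0.25 (SE 0.08, adjusted p = 0.273). When array block was a term, 317 genes were called, including all 267, and within arrays 1 to 11 and 12 to 22 the counts were 145 and 166. The count of 145 rests on 1 KO saline array, with the spread taken from the other groups.

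**Figure D1:**
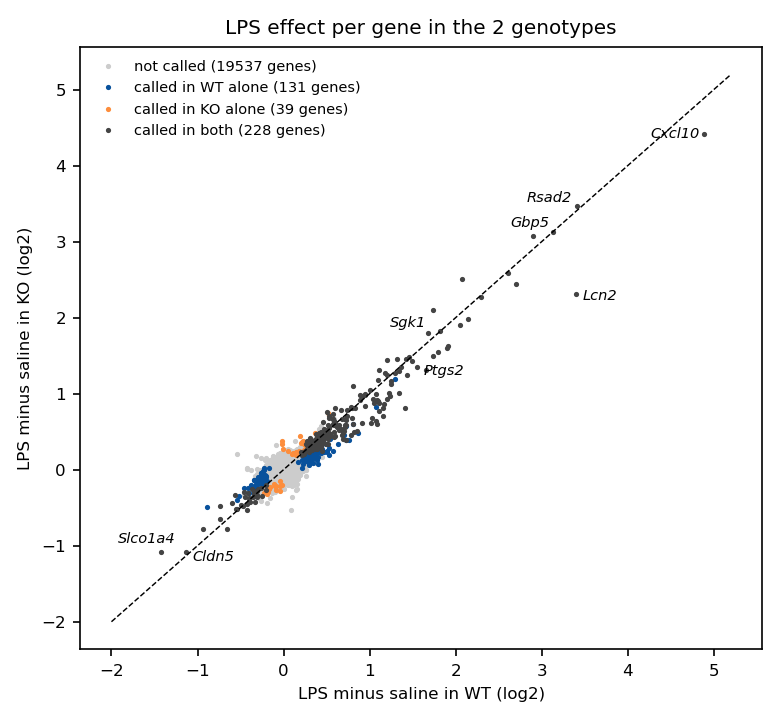
Each point is 1 of 19935 genes, with the log2 difference between LPS and saline in WT on the horizontal axis and in KO on the vertical axis; colours show in which genotype the gene was called, and the dashed line marks equal effects. Rsad2 and Gbp5 lie close to the line, while Lcn2 lies below it at 3.39 in WT and 2.31 in KO.

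The LPS effects of the genotypes, which share no array, were set against each other. The calls do share 1 estimate of the spread per gene over all 22 arrays. The numbers for independent lists therefore serve as a description only. Of the genes called higher, 194 were called in both genotypes, against 3.08 for independent lists of those sizes, with 90 called in WT alone and 22 in KO alone. Of the genes called lower, 34 were called in both, against 0.192 for independent lists, with 41 in WT alone and 17 in KO alone. No gene was called in opposite directions. Across 19935 genes, which are not independent replicates, the effects correlated with Pearson's r of 0.823 and Spearman's rho of 0.353. The score over 396 genes raised by LPS in the averaged effect rose by 0.56 in WT and by 0.50 in KO. The difference of -0.06 did not exceed the spread between arrays (exact permutation p = 0.278, two-sided, 240240 regroupings). For 154 lowered genes the score fell by 0.29 in WT and by 0.26 in KO, a difference of 0.03 (exact permutation p = 0.430). That difference shrank to 0.002 without KO saline replicate 4 and was -0.020 within arrays 1 to 11 (exact permutation p = 0.786), where KO has 1 saline array. Among LPS arrays alone the score of these lowered genes was higher in KO by 0.07 (exact permutation p = 0.000583).

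No single gene passed the interaction test. With limma 0 genes were called and 327 of 19935 had an unadjusted p under 0.05, against 996.75 for a share of 0.05. Other splits of the arrays gave a median of 706 (highest 5429). The smallest p values belonged to Lcn2 (-1.08, SE 0.29), Tmem252 (-0.60, SE 0.18) and the metallothionein Mt1 (-0.34, SE 0.10), whose LPS effects were smaller in KO, and to Bcl6b (0.36, SE 0.08), Dppa5a (0.40, SE 0.10) and H2bu1-ps (0.20, SE 0.05), all with an adjusted p of 0.999994. The same adjusted p held for Il6 (0.15, SE 0.12), Il6ra (-0.06, SE 0.09), Il6st (-0.07, SE 0.08), Socs3 (-0.11, SE 0.11), Il1b (-0.08, SE 0.18) and Tnf (-0.05, SE 0.08). By camera 6 lists differed, 10 without KO LPS replicate 1 or without WT LPS replicate 6, and none with an estimated correlation. The LPS effect over the STAT3-linked and acute-phase list was smaller in KO by 0.12 on average (-0.12, adjusted p = 0.00162, and adjusted p = 0.699 with an estimated correlation). So were those over cytokines and receptors (-0.06, adjusted p = 0.461 with an estimated correlation) and endothelial activation genes (-0.08, adjusted p = 0.699). For circadian clock genes the difference was -0.06 (adjusted p = 0.699), between mean LPS effects of 0.007 in WT and -0.05 in KO. Microglia markers (0.09, adjusted p = 0.461) and choroid plexus markers (0.18, adjusted p = 0.699) differed the other way. The choroid plexus list holds Ttr, which lay at 4.62 in WT saline replicate 1 and at 2.80 in WT LPS replicate 5. Its difference cannot be told apart from carried-over tissue.

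**Figure D2:**
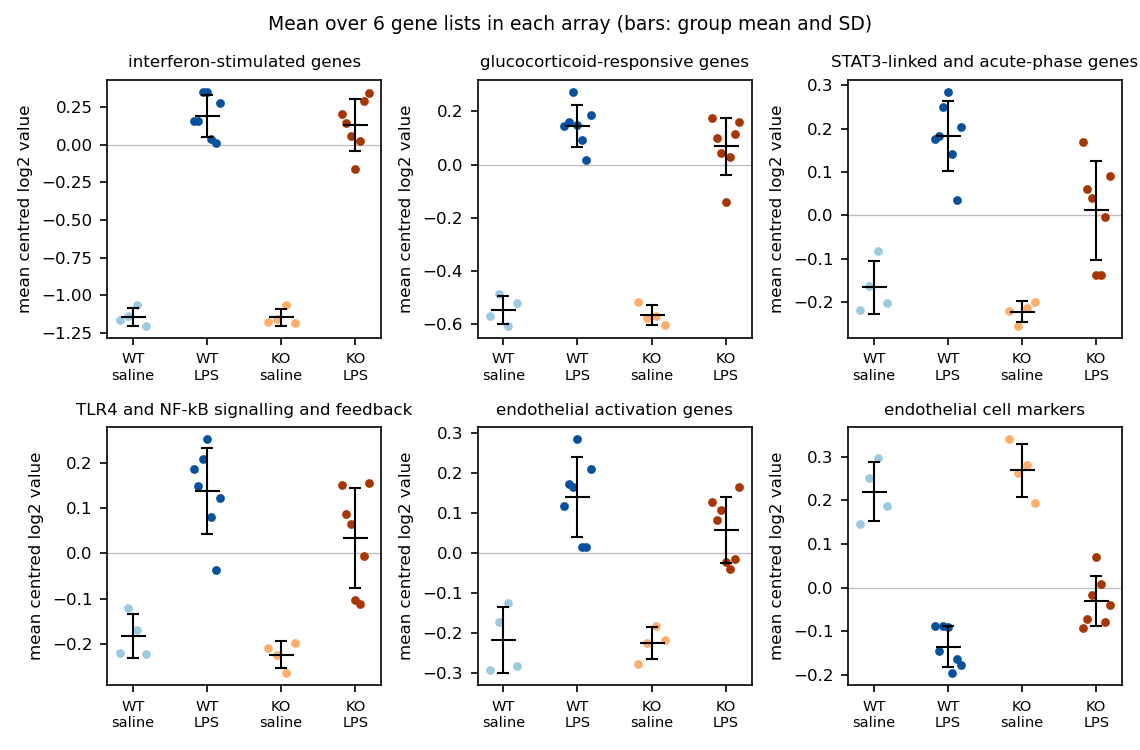
Mean centred log2 value over the measured members of 6 gene lists, 1 point per array, with the group mean and SD; n = 4 for saline and n = 7 for LPS groups. The STAT3-linked and acute-phase mean after LPS was 0.18 ± 0.08 in WT and 0.01 ± 0.11 in KO, while the interferon-stimulated mean was 0.19 ± 0.14 and 0.13 ± 0.17.

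Between the genotypes after LPS, the comparison the study was designed for, 8 genes were called. The 4 lower in KO were all genes that LPS raised in WT, Tmem252 by 1.41 (SE 0.12) and Tgm2 by 1.02 (SE 0.10). Lcn2 was 2.06-fold lower (log2 -1.04, SE 0.17, adjusted p = 0.0164, limma) and Tmem252, a membrane protein gene, was 1.59-fold lower (-0.67, SE 0.11, adjusted p = 0.0136). Tgm2, which encodes the protein-crosslinking enzyme transglutaminase 2, was 1.39-fold lower (-0.48, SE 0.08, adjusted p = 0.0231). Map3k8, a kinase gene of the TLR4 pathway, was 1.35-fold lower (-0.43, SE 0.07, adjusted p = 0.0187). After LPS every KO array lay below every WT array for Lcn2 and Map3k8. The 4 genes higher in KO were Abhd1 (log2 0.46, SE 0.06, adjusted p = 0.000537), the glycosyltransferase Galnt11 (0.37, SE 0.06, adjusted p = 0.0136), the proteasome subunit Psmb5 (0.28, SE 0.05, adjusted p = 0.0164) and the mitochondrial ribosomal protein Mrpl2 (0.25, SE 0.05, adjusted p = 0.0487).

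**Figure D3:**
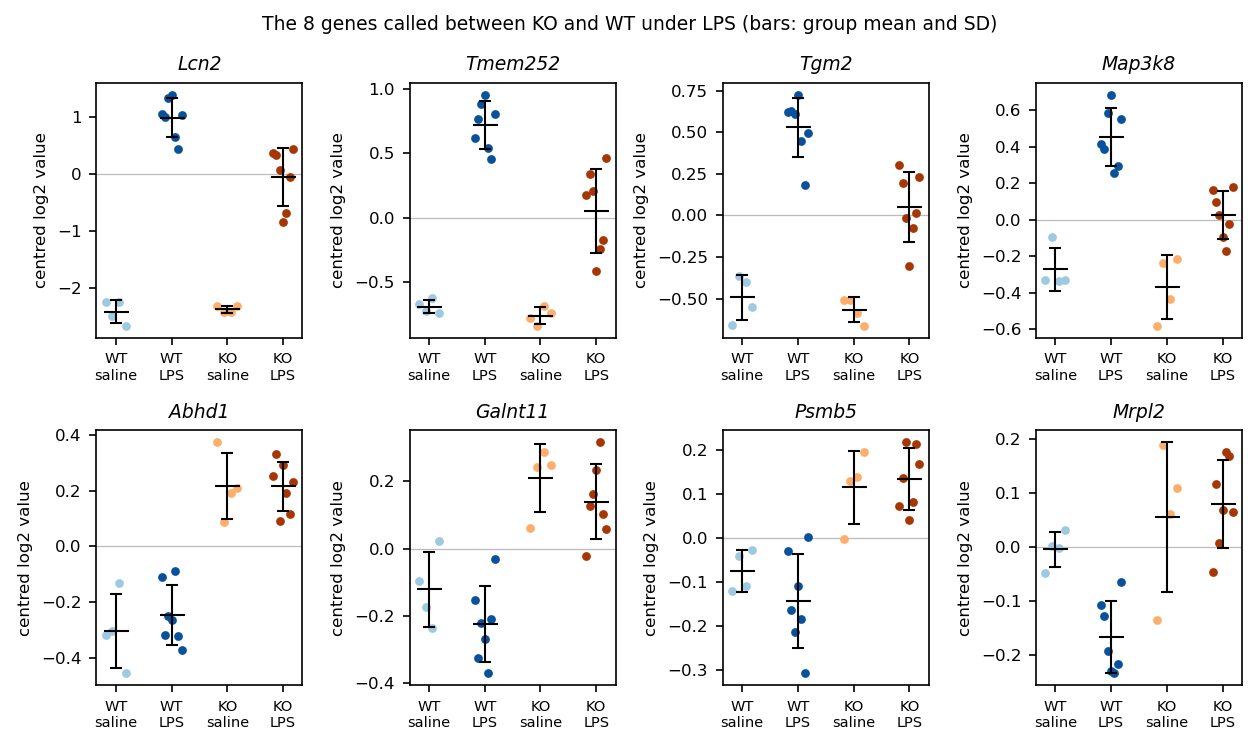
Centred log2 values of the 8 genes called between KO and WT after LPS, 1 point per array, with the group mean and SD. Lcn2, Tmem252, Tgm2 and Map3k8 were near each other in the saline groups and lower in KO after LPS (Lcn2 -0.06 ± 0.51 against 0.98 ± 0.34). Abhd1 was called higher in KO after saline too. Galnt11 and Psmb5 were not called after saline, but averaged over both treatments they were higher in KO by 0.35 (SE 0.05) and 0.23 (SE 0.04).

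Array number bore on these calls. When array block was a term in the fit, 2 genes were called, both within 20 Mb of Il6: Abhd1 (0.53, SE 0.05, adjusted p = 1.81e-06) and Galnt11 (0.30, SE 0.05, adjusted p = 0.0227). Lcn2 then stood at -0.88 (SE 0.16), Tmem252 at -0.61 (SE 0.11), Tgm2 at -0.39 (SE 0.07) and Map3k8 at -0.42 (SE 0.08), each with an adjusted p of 0.0722. With the array number as a covariate 6 of the 8 stayed called, among them Lcn2 (-0.95, SE 0.17, adjusted p = 0.0444), Tmem252 (-0.65, SE 0.11, adjusted p = 0.0417) and Map3k8 (-0.43, SE 0.08, adjusted p = 0.0444), while Tgm2 (adjusted p = 0.0561) and Mrpl2 (adjusted p = 0.108) did not. Within arrays 1 to 11, with 2 KO and 5 WT arrays after LPS, no gene was called and Lcn2 differed by -0.74 (SE 0.15); within arrays 12 to 22, with 5 KO and 2 WT, none was called and Lcn2 differed by -0.95 (SE 0.28). Without the arrays high in Ttr, Gh or Prl 1 gene was called, Abhd1, although Lcn2 then differed by -1.12 (SE 0.20), Tmem252 by -0.72 (SE 0.12), Tgm2 by -0.48 (SE 0.10) and Map3k8 by -0.46 (SE 0.08), with fewer arrays in the fit. Single arrays also moved the count, from 2 genes without KO LPS replicate 6 to 47 without KO LPS replicate 1, and with array weights it was 614.

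Of the genes named beforehand in every comparison, Lcn2 passed this test and the others did not. Ptgs2 differed by -0.40 (SE 0.19, adjusted p = 0.437), Ptges by -0.13 (SE 0.08, adjusted p = 0.523) and Socs3 by -0.18 (SE 0.07, adjusted p = 0.349). Il6ra differed by -0.16 (SE 0.06, adjusted p = 0.344), Il1b by -0.09 (SE 0.11), Tnf by -0.08 (SE 0.05) and Il6st by -0.02 (SE 0.05).

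By camera 14 lists differed between the genotypes after LPS, 7 without KO LPS replicate 4, and none with an estimated correlation. The STAT3-linked and acute-phase list was lower in KO (mean log2 -0.17, adjusted p = 4.8e-11, and adjusted p = 0.230 with an estimated correlation). Of its 28 members, 24 had negative differences, 1 was called over all genes and 13 were lower adjusted over the list alone. The array means over this list differed by the same -0.17 (exact permutation p = 0.00816, adjusted p = 0.0590). They differed by -0.13 (SE 0.04) with array block as a term, and within arrays 1 to 11 and 12 to 22 by -0.09 (SE 0.05) and -0.15 (SE 0.08). TLR4 and NF-kB genes were lower by 0.10 on average (-0.10, adjusted p = 5.05e-05, and adjusted p = 0.342 with an estimated correlation; 3 of 28 lower adjusted over the list alone). That mean was -0.06 (SE 0.04) with array block as a term.

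The other 7 lists lower in KO by camera were the IL-6 family, cytokines and receptors, chemokines, interferon-stimulated genes, endothelial activation genes, glucocorticoid-responsive genes and immediate early genes. Their means lay between -0.09 and -0.04, and their adjusted p with an estimated correlation between 0.342 and 0.635. None of their members was called over all genes; adjusted over the list alone, 4 endothelial activation genes, 2 IL-6 family genes, 2 glucocorticoid-responsive genes, 1 cytokine or receptor, 1 immediate early gene and 1 chemokine were lower, 1 chemokine was higher and no interferon-stimulated gene passed. Il17ra, the closest to a call among them, differed by -0.25 (SE 0.05, adjusted p = 0.0663). The 5 lists higher in KO were cold-inducible RNA-binding genes, endothelial cell markers, microglia and macrophage markers, oligodendrocyte markers and heat-shock genes (adjusted p = 0.230, 0.342, 0.342, 0.471 and 0.405 with an estimated correlation). Cirbp and Rbm3, which encode RNA-binding proteins induced by cooling, differed by 0.26 (SE 0.06, adjusted p = 0.194) and 0.15 (SE 0.05, adjusted p = 0.328), and 3 of the 4 cold-inducible genes were higher adjusted over the list alone. The cold-inducible mean was higher by 0.11 (SE 0.04) with array block as a term, and it was higher after saline as well (0.15, adjusted p = 0.822 with an estimated correlation). Of endothelial cell markers 5 of 16 were higher in KO adjusted over the list alone, with Abcb1a at 0.33 (SE 0.06, adjusted p = 0.0594) and Pecam1 at 0.23 (SE 0.05, adjusted p = 0.0663). Their array mean was higher by 0.10 (exact permutation p = 0.00233, adjusted p = 0.0590), and higher by 0.11 (SE 0.03) with array block as a term; within arrays 1 to 11 and 12 to 22 it was higher by 0.04 (SE 0.05) and 0.16 (SE 0.04). Microglia markers were higher by 0.08 (exact permutation p = 0.00874, adjusted p = 0.0590), with Cx3cr1 at 0.31 (SE 0.07, adjusted p = 0.143), and by 0.07 (SE 0.03) with array block as a term. Adjusted over the list alone, 2 microglia markers, 1 oligodendrocyte marker and 0 heat-shock genes were higher. The other 13 lists did not pass by camera (adjusted p between 0.0564 and 0.917); among them, the prostaglandin E2 list had a median of 0.02 and a mean near 0.

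**Figure D4:**
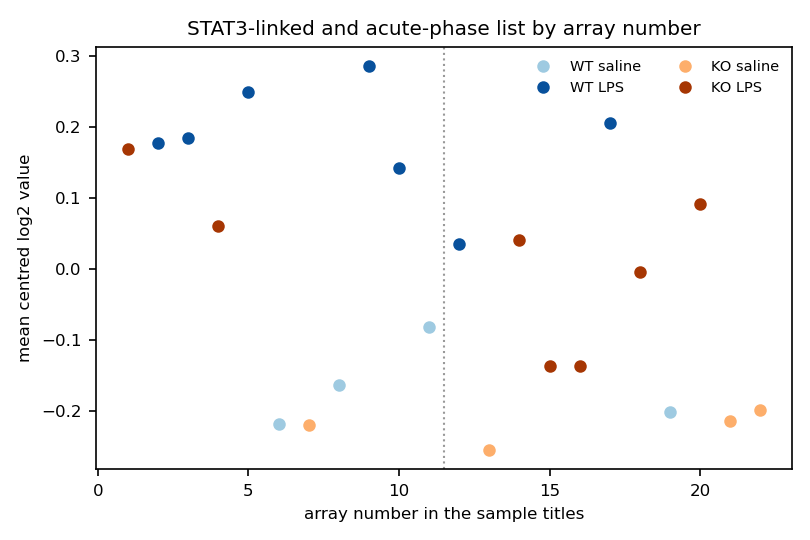
Mean centred log2 value over the 28 STAT3-linked and acute-phase genes, 1 point per array, against the array number in the sample titles; the dotted line separates arrays 1 to 11 from 12 to 22. After LPS the KO mean lay below the WT mean by 0.09 in arrays 1 to 11 (-0.09, SE 0.05) and by 0.15 in arrays 12 to 22 (-0.15, SE 0.08).

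After saline, 1 gene differed between the genotypes: Abhd1 was 1.43-fold higher in KO (log2 0.52, SE 0.07, adjusted p = 0.00825, limma). In all, 1030 of 19935 genes had an unadjusted p under 0.05, against 996.75 for a share of 0.05. Other splits of the saline arrays gave a median of 788.5 (highest 3185). No gene was called without WT saline replicate 1, without WT saline replicate 4 or without KO saline replicate 1. Lcn2 (0.04, SE 0.23), Ptgs2 (-0.20, SE 0.25), Ptges (0.03, SE 0.11), Socs3 (-0.07, SE 0.09), Il6ra (-0.10, SE 0.07), Il1b (-0.007, SE 0.14), Il6st (0.05, SE 0.06) and Tnf (-0.03, SE 0.06) did not pass, with adjusted p values between 0.840 and 0.996. By camera 8 lists differed, and none with an estimated correlation (adjusted p between 0.822 and 0.852 for those lists); 2 differed with array block as a term and 1 without KO saline replicate 1. Cold-inducible, heat-shock and oligodendrocyte genes were higher in KO, and IL-6 family, STAT3-linked and acute-phase, immediate early, choroid plexus and hypothalamic regional genes lower. The choroid plexus list holds Ttr, which lay at 4.62 in WT saline replicate 1, so its difference cannot be told apart from carried-over tissue. Fewer lists differed without the arrays high in Ttr, Gh or Prl.

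Averaged over both treatments 5 genes were called between the genotypes: Abhd1 (0.49, SE 0.05), Galnt11 (0.35, SE 0.05), Otof (-0.38, SE 0.06), Rrs1 (0.55, SE 0.08) and Psmb5 (0.23, SE 0.04). Rrs1 and Psmb5 are named outside the rule, after their values were seen. Abhd1, Galnt11 and Otof lie within 20 Mb of Il6 on chromosome 5 of the reference, with 22, 21 and 7 tested genes between them and Il6. Of 19852 placed genes 249 lie in that window, so 3 of 5 exceeded the share of other genes (Fisher's exact test, odds ratio 119, p = 1.91e-05, two-sided). Fitted with array block as a term, 3 genes were called, 2 of them in the window (Fisher's exact test, p = 0.000466). When the arrays high in Ttr, Gh or Prl were left out, Abhd1 alone stayed called (Fisher's exact test, p = 0.0125), while Galnt11 stood at 0.33 (SE 0.06, adjusted p = 0.0899), Otof at -0.38 (SE 0.07, adjusted p = 0.128), Rrs1 at 0.54 (SE 0.09, adjusted p = 0.0899) and Psmb5 at 0.21 (SE 0.05, adjusted p = 0.497). Leaving out KO LPS replicate 1 gave 12 called genes near Il6. For Abhd1 each of the 11 KO arrays lay above each of the 11 WT arrays.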

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

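Several tests were chosen after the results they weigh were seen. They were the tests of array order around Il6 and on the STAT3-linked list, and of an effect of IL-6 loss anywhere in the genome. The tests of endothelial cell share and of tissue carry-over were also among them, as were the splits within array blocks and the splits for unadjusted p. The other tests were written down before. Of these, the share of other genes near Il6 and the test of array order on the excess of small p used array block as a term. That term was added after the array numbers were seen to be partly confounded with genotype.

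Of 5 genes called between the genotypes over both treatments, Abhd1, Galnt11 and Otof lie within 20 Mb of Il6. Array order as the whole cause is argued against for Abhd1 (0.56, SE 0.04) and Galnt11 (0.28, SE 0.04), which stayed called with array block as a term. The smallest ratio of a difference to its SE there was 5.47, for Otof, whose call was lost (-0.35, SE 0.06, adjusted p = 0.0738, limma). The genes were chosen on the same arrays, so these ratios may be too high. An effect of IL-6 loss acting alike on genes anywhere would not favour the window around Il6. The fit with array block as a term called 2 genes in the window and 1 elsewhere (Fisher's exact test, p = 0.000466). That test repeats the pattern on the same arrays with few genes, so it is no separate evidence against such an effect. Alleles of another strain kept around the altered gene are a candidate explanation: of the 246 other genes near Il6, 15.04% had an unadjusted p under 0.05 in that fit against 5.70% elsewhere (permutation p = 0.0025 over 2000 rotations of the gene order). An effect of the altered locus on its neighbours, and probes that mismatch another strain's alleles, stay open as untested.

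The STAT3-linked and acute-phase list was lower in KO after LPS. Array order as the whole cause is argued against by the difference of -0.13 (SE 0.04) with array block as a term, although within each block the difference was less than 2 SE from 0. A smaller LPS response throughout, with no difference before LPS, would leave about 0 after scaling by the response of 382 other raised genes. The LPS arrays kept -0.13 (exact permutation p = 0.00117), and -0.10 (SE 0.03) with array block as a term, which argues against that combination. That comparison used LPS arrays alone. By camera at the preset correlation the list was lower in KO after saline too, so part of the -0.13 may be present without LPS. The difference in LPS effect left after scaling was not tested, so a smaller LPS response added to a difference before LPS stays open. Fewer endothelial cells in KO tissue cannot be told apart, because LPS itself lowered their markers by 0.36 in WT and by 0.30 in KO: after LPS these were higher in KO by 0.10 (exact permutation p = 0.00233, adjusted p = 0.0590), and after saline by 0.05 (exact permutation p = 0.314). A genotype effect on this list may remain as a hypothesis, found and tested on the same arrays, and the list's call was lost with an estimated correlation.

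Between the genotypes after LPS, 2267 genes had an unadjusted p under 0.05, against 996.75 for a share of 0.05 and a median of 615 in other splits of the LPS arrays. Array order is a candidate explanation for the excess: with array block as a term the number was 1030, and with the array number as a covariate 1295. Tissue carried over from choroid plexus or pituitary cannot be told apart from the loss of arrays: without the 4 arrays high in Ttr, Gh or Prl the number was 1323, and 6 of 50 random draws that left out 4 other arrays gave a number as low (range 1177 to 4690). Of 100 splits, 10 gave 2267 or more (highest other 5567), and of 100 splits within the blocks, fitted with the block, 38 gave 1030 or more (highest other 2506), so chance cannot be excluded for either number. With the block little excess was left, but block and genotype are partly confounded, so the block may have taken up part of a genotype effect.

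Other splits of the same arrays were run for each count. For LPS in WT 1 of 100 splits, the real one, gave 359 genes or more, and the highest other gave 1; for LPS in KO 1 of 100 gave 267 or more, and the highest other gave 2, so chance can be excluded for both. For KO against WT after LPS 3 of 100 splits, the real one among them, gave 8 genes or more, and the highest other gave 973. That highest split put 1 and 6 of the arrays numbered 12 to 22 in its groups, which points to a structure of the arrays by number. The splits ignored that number, so they do not exclude chance for the 8 genes. With array block as a term the count was 2. Of 100 splits that kept the KO arrays in each block, drawn from 441 and fitted with the block, 3 gave 2 genes or more. The real split was among them and the highest other gave 3, which makes chance less likely for that count but does not exclude it. For KO against WT after saline 3 of 35 splits gave 1 gene or more and the highest other gave 267, with 0 and 4 of the later arrays in its groups, so chance cannot be excluded. For the interaction the count was 0, which all 100 of 100 splits reach, so these splits test nothing; the highest other gave 1422. For lists by camera at the preset correlation, a small share of splits reached the count for KO against WT after LPS. This held in splits that ignore the array number (14 lists, 3 of 100 as many, highest other 18) and in splits within the blocks (13 lists with the block, 3 of 100, highest other 16). Other splits exceeded both counts, so chance is less likely but not excluded for these lists. With an estimated correlation none of these lists was called (lowest adjusted p = 0.230), and within the blocks alone 2 and 6 were. Chance cannot be excluded for the number of lists called for LPS in WT (14 lists, 8 of 100, highest other 15), LPS in KO (12 lists, 27 of 100, highest other 17), KO against WT after saline (8 lists, 2 of 35, highest other 8) or the interaction (6 lists, 38 of 100, highest other 17). This concerns the numbers of lists: interferon-stimulated and glucocorticoid-responsive genes, for example, passed with an estimated correlation for LPS in each genotype, and their array means gave an exact permutation p of 0.00303, the lowest of 330 regroupings (adjusted p = 0.00909 in WT and 0.0205 in KO).

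The LPS effect differed between the genotypes by camera's test of the interaction for 6 lists: STAT3-linked and acute-phase genes (adjusted p = 0.00162), cytokines and receptors (0.00253), endothelial activation genes (0.0231), clock genes (0.0381), microglia markers (0.00507) and choroid plexus markers (0.00507). None of these passed with an estimated correlation. For choroid plexus markers, tissue carried over into WT saline replicate 1 and WT LPS replicate 5 cannot be told apart from an LPS effect.

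Single arrays lay far from the others of their group in 18 of 456 groups of values tested, where chance gives 22.8. Among genes, WT LPS replicate 5 had 0.16 for Bcl6b and -0.49 for Cirbp, and KO LPS replicate 4 had -0.46 for Fkbp5 and -0.73 for Zbtb16. WT saline replicate 2 had 0.10 for Hpgd and -0.093 for Map3k8, and WT saline replicate 4 had -0.89 for Vcam1. KO saline replicate 1 had -2.55 for Iigp1, replicate 2 had -0.29 for Mt1 and replicate 4 had 0.16 for Socs3. Among list means, WT saline replicate 2 had -0.022 for the prostaglandin E2 list, WT saline replicate 4 had 0.068 for cold-inducible genes and WT LPS replicate 4 had 0.014 for microglia markers. KO saline replicate 3 had 0.080 for heat-shock genes, KO saline replicate 2 had 0.90 for pituitary markers, and KO LPS replicate 3 had -0.12 for clock genes and -0.30 for thalamus and telencephalon markers. The score of lowered genes was -0.15 in WT LPS replicate 5.

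Of the 7035 probe sets with no or several symbols, which the gene comparisons left out, 64 were called for LPS in WT, 63 of them higher, and 54 for LPS in KO, 53 of them higher.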

How the results depend on the processing

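The alternatives with array number, array block, carry-over arrays, level, robust moderation, another probe set per gene and permuted list means were chosen after seeing the data; the others were planned. The planned filter on dim genes and the variance trend were not run, because centring removed the levels. As a stand-in for the filter, a level of 8 or more was inferred from the step between the values of a probe set. Arrays 1 to 11 hold 1 KO saline array and arrays 12 to 22 hold 1 WT saline array, so values within these blocks that use those groups rest on 1 array, assumed to vary like the others. No paired analysis was possible because the labels pair no arrays. Where a value moved, the cause was not tested, except that the fold threshold, the level limit, the blocks and left-out arrays hold fewer genes or arrays by construction.

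Genes called between KO and WT after LPS (8) were 16 after another quantile normalization, 614 with array weights, 2 at 1.5-fold or more, 1 with only the groups compared, 1 with the unmoderated test with unequal variances, 5 among 3805 genes at a level of 8 or more, 6 with the array number as a covariate, 2 with array block as a term, 0 within arrays 1 to 11, 0 within arrays 12 to 22 and 1 without the carry-over arrays. Genes called for LPS in WT (359) were 115 at 1.5-fold, 196 with the unmoderated test, 55 at a level of 8 or more and 45 within arrays 12 to 22. For LPS in KO (267) they were 96, 116, 46 and 166 there, and 145 within arrays 1 to 11. The 1 gene after saline became 0 after quantile normalization, at 1.5-fold, with only the groups compared, with the unmoderated test, at a level of 8 or more and within each block. The interaction gave 0 in every setting run.

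Lists between KO and WT after LPS (14) were 2 within arrays 1 to 11, 6 within arrays 12 to 22, 0 with an estimated correlation, 2 with fry and 0 with permuted list means. After saline (8) they were 5 after quantile normalization, 5 with centred arrays, 2 with the block, 2 and 1 within the blocks, 4 without the carry-over arrays, and 0 with an estimated correlation, fry or permuted means. For the interaction (6) they were 10 after quantile normalization, 3 and 2 within the blocks, 2 without the carry-over arrays, and 0 with an estimated correlation, fry or permuted means. The correlation of LPS effects (0.823, jackknife SE 0.0561) was 0.702 after quantile normalization, 0.572 and 0.525 within the blocks and 0.749 without the carry-over arrays. The genotype difference in the LPS response score turned to 0.020 within arrays 1 to 11, with its 1 KO saline array (exact permutation p = 0.810), and that of lowered genes to -0.20 (exact permutation p = 0.0714), on genes chosen anew in that block. On the genes chosen over all arrays the differences there were -0.036 (exact permutation p = 0.583) and -0.020 (exact permutation p = 0.786), and within arrays 12 to 22 they were -0.059 and 0.014.

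Leaving out each array in turn gave 2 to 47 genes for KO against WT after LPS: 47 without KO LPS replicate 1, 2 without KO LPS replicate 6, 4 without WT LPS replicate 3, WT LPS replicate 4 or KO LPS replicate 3, and 5 without KO LPS replicate 4 or 5. The ranges were 288 to 367 for LPS in WT, 209 to 292 for LPS in KO and 0 for the interaction. After saline the range was 0 to 2, with 0 without WT saline replicate 1 or 4 or KO saline replicate 1, and 2 without WT LPS replicate 4 or 7. The Il6 difference ranged from 0.10 to 0.21, the score from -0.09 to -0.03, the score of lowered genes from 0.002 to 0.05, the genes near Il6 from 3 to 12 and the correlation from 0.787 to 0.830. Lists ranged from 7 (without KO LPS replicate 4) to 15, 12 to 15, 11 to 15, 1 (without KO saline replicate 1) to 8, and 4 to 10 (without KO LPS replicate 1 or WT LPS replicate 6) over the 5 comparisons as ordered in the methods. Of values for named genes, 4926 kept their direction and side of the threshold, 256 lost it, 24 gained it, 33 uncalled values moved and 0 called values changed sign. Calls were lost most often for Mrpl2 (KO against WT after LPS, 23 of 31 alternatives), Ptges and Ccl2 (LPS in WT, 20 and 19), Tgm2 (KO against WT after LPS, 13) and Tnfaip3 (LPS in KO, 13).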

Other observations

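Averaged over both genotypes, LPS changed 550 genes, 396 higher and 154 lower. Of the 396 raised genes, 265 (66.9%) had a smaller LPS effect in KO. Genes are not independent replicates, and the difference in LPS effect of their score did not exceed the spread between arrays (-0.06, exact permutation p = 0.278). Among LPS arrays alone the score of lowered genes was higher in KO by 0.07 (exact permutation p = 0.000583, two-sided), by 0.07 (SE 0.02) with array block as a term, and by 0.04 (SE 0.02) and 0.07 (SE 0.04) within arrays 1 to 11 and 12 to 22. That of raised genes differed by -0.07 (exact permutation p = 0.154), and by -0.06 (SE 0.04) with array block as a term. After saline the score of lowered genes was already higher in KO, at 0.21 against 0.17 in WT. Its LPS effect differed between the genotypes by 0.03 (exact permutation p = 0.430).

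The LPS arrays alone, split into 7 with lower and 7 with higher numbers, gave 4493 called genes, and the array number within the 4 groups was related to 3313 genes. The labels do not say what the number stands for.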
